A study of Mus musculus with 12 samples.

How the data were processed

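RNA from the left ventricular area at risk of mouse hearts was hybridized to 12 Affymetrix mouse arrays, with 3 arrays in each of 4 groups: wild type and A2BAR knockout, each as control hearts and as hearts exposed to ischemic preconditioning (IP). Groups were taken from the sample labels. The deposited value table holds 1 array signal intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes; the scaling target is not given in the sources used here. The authors' deposited table of a test over all groups holds a mean log2 expression, an F score, a p-value with its adjusted form, a decision score of −1, 0 or 1 and a log2 difference for each of 5 contrasts, per the file headers; how those log2 values were summarized is not stated. The authors' lists per contrast hold the probe sets whose decision was not 0 and whose change was at least 2-fold, as tested on the tables. No raw scans were analysed here.

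The third wild-type control array has an unbroken run of 1425 probe sets with a signal of 0, and the same probe sets have a median signal of 659 on the other arrays. They were treated as missing on that array, since runs of at least 100 zeros were set as missing. The 64 Affymetrix control probe sets were left out of the tests. The remaining 45037 probe sets were transformed to log2(signal + 16), and a fold change is therefore a ratio of signals plus 16, which is smaller than the ratio of signals where signals are low. Probe sets with a mean above the 40th percentile (27022) were kept. Each gene was represented by its brightest probe set, among probe sets annotated with exactly 1 symbol (40137 of 45037; 1232 have several symbols and 3668 none). Symbols were updated by Entrez identifier in an NCBI RefSeq gene table, used for names only: 36287 probe sets matched, 7947 symbols changed, and 3850 symbols were kept as in the authors' table. This gave 14044 genes, of which 13192 had values on all 12 arrays and 852 lacked the third wild-type control array. Positions are those of the authors' table, whose genome build is not given in the sources used here.

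A model with 1 mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, which leaves 8 residual degrees of freedom, with empirical Bayes moderation and a trend of the variance with intensity. Tests were two-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene passed at an adjusted p below 0.05. The contrasts were IP against control in each genotype, knockout against wild type in each treatment, the difference between the genotypes in their IP effect, and the average IP and genotype effects. Errors of log2 changes are standard errors (SE) from limma. A gene is called separate when all 3 arrays of a group lie on 1 side of all 3 arrays of the other. The numbers of the replicates were checked for pairing, and the arrays were treated as unpaired. That check is given with the settings. The labels do not say whether the arrays of a group come from separate animals, so p-values measure only the spread between these samples.

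The genes named in the text were chosen by a rule: for each IP comparison, the 12 largest rises and the 8 largest falls among separate genes past the threshold; for each genotype comparison, 8 of each; for the difference, up to 10 genes past the threshold or else the 5 with the smallest p; up to 4 members of each gene list past the threshold, or else the 2 with the smallest p; and the adenosine receptors, Per1 and Per2 in every comparison. RIKEN, Gm and LOC symbols were passed over. Some genes that the rule names are not reported here. In every IP and genotype comparison 26 lists of genes were tested, 16 of pathways and 10 of cell types, with 441 entries. The lists cover immediate-early genes, cytokines and adhesion molecules, the circadian clock, glycolysis, hypoxia, fatty acid oxidation, the tricarboxylic acid cycle with oxidative phosphorylation, heat shock, endoplasmic reticulum stress, antioxidants, the adenosine pathway, cAMP targets, cardiac stress, p53 and growth arrest, ion channels, the interferon response, cardiomyocytes, atrial cells, endothelial cells, fibroblasts, mural cells, neutrophils, monocytes and macrophages, lymphocytes, adipocytes and erythroid cells. A list was compared with all other genes by limma's camera on the moderated statistics with a preset correlation of 0.01, in the form that takes a ranking, because the form planned takes no missing values. The form with an estimated correlation and limma's fry were run on the genes with values on all arrays, and adjusted p-values are over the 26 lists. The lists, the contrasts, the rule for named genes and most alternatives were fixed before the data were examined.

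The alternatives were offsets of 1 and 64, quantile normalization, no filter and a filter at the 60th percentile, no intensity trend, robust moderation, array weights, the mean of all probe sets of a gene, replicate numbers as a block, fits of only the groups compared, a 2-fold minimum, and leaving out each array in turn. Where the array left out belongs to neither group compared, the log2 changes stay the same and only the estimate of spread moves. After the data were seen, 2 alternatives were added: the run of zeros kept as deposited, and the log2 ratio of the 3' to the 5' beta-actin control probe sets of each array as a covariate. Planned use of the authors' per-array values was not possible from the sources used here. The pipeline was tested on simulated data with values drawn around the real means and spreads of 14044 genes, independently for each gene. Changes of 0.5, 1 and 2 log2 were given to 67, 67 and 66 genes. Recovery depends on the share of genes changed and on correlation between genes, so these rates need not hold for the real arrays. In simulated changes for IP against control in wild type, limma recovered 22.4% of changes of 0.5 log2, 62.7% of changes of 1 log2 and 90.9% of changes of 2 log2, with 8 false calls among 125. In simulated changes for knockout against wild type after IP, it recovered 25.4%, 64.2% and 92.4%. For the difference in IP effect it recovered 7.46%, 44.8% and 80.3%.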

Results

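Gene expression was measured on 12 Affymetrix arrays in the left ventricular area at risk of male mice aged 12 weeks. The mice were wild type or lacked A2BAR, the adenosine A2B receptor, which is encoded by Adora2b and raises cAMP when extracellular adenosine binds. IP consisted of 4 rounds of 5 min of ischemia, each ended by 5 min of restored flow, and the tissue was taken after a final 2 h of reperfusion. There were 3 arrays each of wild-type control, wild-type IP, knockout control and knockout IP hearts. The labels call the control mice untreated in the design text and sham operated in the treatment text, and they describe the wild-type mice both as bought from a vendor and as littermates. If the controls were untreated, every difference between IP and control hearts also holds that of the surgery, and if the wild-type mice were bought, every difference between the genotypes also holds that of their background. Median signals were between 66.5 and 81.1 units per array, and rank correlations between arrays of a group were between 0.908 and 0.919. The number of arrays limits the precision of each value.

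Adora2b, the targeted gene, had lower signals in the knockout than in the wild-type hearts over both treatments, and whether its knockout signals lie above background was not tested. Its brightest probe set read 61.7 ± 17 units in wild-type control hearts, 176 ± 27.4 in wild-type IP hearts, 44.4 ± 23 in knockout control hearts and 53.9 ± 7.03 in knockout IP hearts (mean ± SD, n = 3 each). Over both treatments the knockout arrays were lower by log2 −0.94 ± 0.25 (SE; exact permutation p = 0.0346, two-sided, 924 permutations). Its adjusted p over all probe sets by limma was 0.162. The other 3 probe sets of the gene gave exact permutation p-values of 0.0801, 0.0931 and 0.106 (two-sided). Whether any of them lies in the deleted part of the gene is not given in the sources used here, so these values are a weak check of the genotype labels. The gene lies on chromosome 11 from 62065179 to 62082647 in the authors' table.

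The comparison of IP with control hearts in wild type asks how the ventricle responds to preconditioning when the receptor is present. Of the separate genes past the threshold, Il6, a cytokine released early after tissue injury, had the largest rise and was 274-fold higher (log2 8.10 ± 0.38 SE, limma adjusted p = 1.1e-08, n = 3 arrays per group). Its wild-type control arrays read only 5.32, 4.87 and 5.74 log2. Whether the control signals of the risers lie above background was not tested. Where control signals are low, the fold change and rank of a riser depend on the offset added before the log. The chemokines Cxcl2, Cxcl5 and Cxcl1, which attract neutrophils, rose by 6.49 ± 0.48, 5.56 ± 0.34 and 5.01 ± 0.39 log2, and the macrophage chemokine Ccl3 rose by 4.41 ± 0.54. Atf3, a transcription factor induced by many stresses, rose 42.1-fold (5.40 ± 0.22), and Ptx3, a secreted pattern-recognition protein, rose 33.5-fold (5.07 ± 0.36). Cxcl3, Sphk1, which makes sphingosine-1-phosphate, Csf3, the growth factor of granulocytes, and Arc, an activity-regulated early gene, rose by 4.01 ± 0.39, 3.97 ± 0.30, 3.94 ± 0.31 and 3.87 ± 0.54. Of the genes that fell, Pcdh12, a protocadherin of endothelial junctions, changed by −2.89 ± 0.32 log2, Aplnr, the apelin receptor, by −2.68 ± 0.33, and Upk3b, a mesothelial gene, by −2.57 ± 0.49. In each of these genes all 3 IP arrays lay on 1 side of all 3 control arrays.

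By limma, 2328 of 14044 genes passed between wild-type IP and control hearts, 918 higher and 1410 lower. The count was 1420 without the first wild-type IP array and 2016 without the third wild-type control array. Of the genes past the threshold, 369 were at least 2-fold higher and 198 at least 2-fold lower. Arrays did not overlap between IP and control in 33.5% of genes, against 10% by chance. Angptl4, Cd14, Fosl1, Ier2, Klf4, Per2 and Pfkfb3 had no usable value on the third wild-type control array, so their values against wild-type control hearts rest on 2 control arrays.

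The cytokine and adhesion list rose almost as a whole in wild-type IP hearts: of 28 genes, 26 rose and 2 did not pass, with 27 higher adjusted over the list alone. For IP, where only the counts over all genes are given for a list, those adjusted over the list alone are equal to them. Its median change was 2.52 log2 (camera adjusted p = 2.57e-38; adjusted p = 0.00473 with an estimated correlation). Of the 14 neutrophil markers, 13 rose, and the same number did adjusted over the list alone, with a median of 2.75 (adjusted p = 5.94e-13; adjusted p = 0.0837 with an estimated correlation). Among wild-type control arrays the third stood apart in several of these markers, with S100a9 at 12.24 log2 against 8.41 and 8.28, Mmp8 at 8.05 against 6.12 and 5.75, and Il1r2 at 7.61 against 6.30 and 6.09. Trem1, which amplifies neutrophil activation, rose by 3.50 ± 0.38, and the lectins Clec4e and Clec4d rose by 3.85 ± 0.52 and 3.60 ± 0.51. S100a9, an abundant protein of neutrophils, changed by 3.38 ± 0.77 (adjusted p = 0.00823), although its arrays overlapped between the groups and robust moderation ended its call (adjusted p = 0.0595). Among monocyte and macrophage markers 1 of 16 rose and 2 fell (median 0.036, adjusted p = 0.366), and the riser was Cd14, the co-receptor for endotoxin, at 2.73 ± 0.15. The interferon list did not move as a group, with 2 of 14 genes higher and 1 lower. Its median was −0.174, its mean 0.103, and camera pointed up (adjusted p = 0.502). The risers were Cxcl10 at 2.22 ± 0.22 and the transcription factor Irf1 at 1.17 ± 0.15.

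Immediate-early genes, which cells transcribe within minutes of a stimulus, went both ways in wild-type IP hearts. Of 30 genes, 18 rose and 4 fell, the same counts adjusted over the list alone, and the median was 1.26 (adjusted p = 1.1e-11; adjusted p = 0.0341 with an estimated correlation). Fosl1, a partner of Jun, rose by 3.36 ± 0.44 and Myc, a growth regulator, by 3.14 ± 0.23. The early transcription factor Egr3 fell by 1.91 ± 0.41 log2. The other fallers, chosen after their values were seen, were Klf2 (−1.09), Klf4 (−1.01) and Ier2 (−0.68), of which Klf2 and Klf4 are shear-responsive factors of the endothelium. The call of Ier2 ended without the first, the second or the third IP array (adjusted p = 0.0777, 0.0806 and 0.0771) or the second control array (0.238), a fit that left 1 control array for this gene and took the spread from the other groups. It also ended without an intensity trend (0.0955) and with the mean of all probe sets (0.0505). In the cAMP target list 5 of 13 genes rose and 1 fell (5 and 1 adjusted over the list alone; median 0.539, adjusted p = 0.000112; adjusted p = 0.0341 with an estimated correlation). They included Fosl2, another partner of Jun, at 1.49 ± 0.30 and Pde4b, which breaks down cAMP, at 1.10 ± 0.16. Of 14 cardiac stress genes 8 rose (median 0.72, adjusted p = 4.32e-08; adjusted p = 0.0434 with an estimated correlation), and 9 were higher and 1 lower adjusted over the list alone. Hbegf, an injury-induced growth factor, rose by 3.12 ± 0.26 and Xirp1, a protein of intercalated discs, by 2.13 ± 0.17. Of 13 antioxidant genes 7 rose, as adjusted over the list alone (median 0.402, adjusted p = 6.61e-06; adjusted p = 0.0341 with an estimated correlation). The metal-binding Mt2 and Mt1 rose by 3.28 ± 0.33 and 1.65 ± 0.20, and Hmox1, which degrades heme, rose by 2.40 ± 0.48.

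The calls of the p53, endoplasmic reticulum stress, hypoxia, glycolysis and fatty acid oxidation lists in wild-type IP hearts ended with an estimated correlation. Of 16 p53 and growth-arrest genes 6 rose (median 0.267, adjusted p = 0.00479; adjusted p = 0.185 with an estimated correlation), among them Gadd45g at 2.24 ± 0.28 and Bcl2l1, which opposes apoptosis, at 1.61 ± 0.25. Of 16 endoplasmic reticulum stress genes 3 rose (median 0.205, adjusted p = 0.00479; adjusted p = 0.369 with an estimated correlation), with Ppp1r15a, a phosphatase subunit that ends the block of translation, at 1.94 ± 0.13. In the hypoxia list 9 of 22 genes rose and 4 fell (9 and 5 adjusted over the list alone; median 0.136, adjusted p = 0.0124; adjusted p = 0.369 with an estimated correlation; adjusted p = 0.108 without the second wild-type control array). Angptl4, an inhibitor of lipoprotein lipase, rose by 3.45 ± 0.58. Of 20 glycolysis genes 3 rose and 1 fell (median 0.0632, adjusted p = 0.0365; adjusted p = 0.47 with an estimated correlation). Pfkfb3, which makes an activator of glycolysis, rose by 3.09 ± 0.27, and Pfkfb2, which does the same in heart, fell by 1.21 ± 0.26 log2. Without the third IP array, the first control array or the second control array the adjusted p of the glycolysis list was 0.0916, 0.0866 or 0.0893, and with quantile normalization it was 0.532. Of 22 fatty acid oxidation genes 4 rose (median 0.108, adjusted p = 0.00317; adjusted p = 0.411 with an estimated correlation). They included Ppargc1a, a coactivator of mitochondrial genes, at 1.33 ± 0.12. That list's adjusted p was 0.0865 without the second control array and 0.442 with quantile normalization.

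Genes of the contractile and respiratory machinery were slightly higher after IP in wild type, calls that quantile normalization ended. Total signals on probe sets with values on all arrays were highest on the wild-type IP arrays (37287858 to 37455385 units; highest elsewhere 36540277). The main fit used no normalization between arrays. All genes of both lists exceeded the median gene in wild-type control hearts, so these shifts cannot be told apart from brighter arrays. Of 22 cardiomyocyte genes 11 rose, and 16 were higher and 1 lower adjusted over the list alone (median 0.197, adjusted p = 6.24e-07; adjusted p = 0.185 with an estimated correlation). Actc1, the cardiac actin, and Csrp3, a Z-disc protein, each rose by 0.25 log2 (SE 0.05 and 0.06), and with quantile normalization both calls ended (0.04 and 0.09), as they did without an intensity trend (adjusted p = 0.0722 and 0.0816). Of 23 genes of the tricarboxylic acid cycle and oxidative phosphorylation 6 rose, or 13 adjusted over the list alone (median 0.142, adjusted p = 6.61e-06; adjusted p = 0.369 with an estimated correlation). Quantile normalization ended the cardiomyocyte call (adjusted p = 0.707) and turned the respiratory list to the opposite direction (adjusted p = 0.939). Of 5 erythroid genes 1 rose, or 2 adjusted over the list alone (median 0.616, adjusted p = 0.0365; adjusted p = 0.369 with an estimated correlation). Its adjusted p was 0.127, 0.0634 and 0.129 without the third IP array, the first control array or the second control array, and 0.231 with no filter on low values.

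The adenosine pathway list did not move as a group in wild type: of 13 genes 4 rose and 1 fell, or 5 and 3 adjusted over the list alone (median 0.0486, camera adjusted p = 0.303). Nt5e, the ectoenzyme that makes adenosine from AMP, rose by 1.45 ± 0.27. Adora2b itself was 2.49-fold higher (1.32 ± 0.33, adjusted p = 0.0135), and its adjusted p was 0.0632 without the first IP array and 0.0569 without the first control array. Adora1 and Adora2a, the receptors of higher affinity, had changes of 0.58 ± 0.28 (adjusted p = 0.18) and 0.05 ± 0.26 (adjusted p = 0.928). Without the second control array Adora1 was at 0.29, and with 1 array left out Adora2a ranged from −0.10 to 0.26. Of 19 clock genes 7 rose and 1 fell, or 11 and 3 adjusted over the list alone (median 0.547, adjusted p = 0.00229; adjusted p = 0.0536 with an estimated correlation). Ciart, a clock repressor, rose by 3.08 ± 0.72, a call that robust moderation ended (adjusted p = 0.0524). Per2, a core repressor of the clock, rose by 2.41 ± 0.67 (adjusted p = 0.0256), with adjusted p = 0.0917 without the third IP array and 0.17 without the second control array, which left 1 control array for Per2, assumed to vary like the other groups. Its adjusted p was 0.0809 without an intensity trend and 0.0924 with robust moderation. Per1 rose by 0.54 ± 0.16 (adjusted p = 0.0345). Its adjusted p was 0.0604, 0.0588 and 0.12 without the first, the second or the third IP array, and 0.134 and 0.0989 without the first or the second control array. It was 0.0678 without an intensity trend, 0.0507 with replicate numbers as a block and 0.0676 with zeros kept.

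In the other lists of wild-type IP hearts few genes passed. Heat shock genes had 2 of 15 higher and 1 lower (median 0.0139, adjusted p = 0.263); Hspb1, a small chaperone, rose by 0.66 ± 0.11 (adjusted p = 0.0879 with the mean of all probe sets) and Chordc1, a partner of Hsp90, fell by 0.69 ± 0.15 log2. Without the third wild-type control array the heat shock list had an adjusted p of 0.0107 and the monocyte and macrophage list one of 0.0377. Of 16 endothelial genes 1 rose and 4 fell (median −0.11, adjusted p = 0.263; by fry, which compares with no other genes, adjusted p = 0.0309, lower), with Egfl7, a secreted vessel protein, at −1.17 ± 0.15 and Kdr, a receptor of VEGF, at −1.07 ± 0.21. Ion channel genes had 2 of 19 higher and 2 lower, with a median of −0.0516, a mean of 0.000716 and an adjusted p of 0.959. Of 14 fibroblast genes 1 fell (median −0.219, adjusted p = 0.0916; adjusted p = 0.0194 without the second wild-type IP array and 0.00201 without the first wild-type control array, 0.0131 with no filter on low values and 0.0313 with the beta-actin covariate), and of 11 mural genes 1 fell (median −0.0407, adjusted p = 0.502). Of 5 adipocyte genes 1 rose (median 0.117, adjusted p = 0.366); it was Lipe, a lipase of fat stores, at 0.74 ± 0.15. The 4 atrial genes (median 0.215, adjusted p = 0.263) and the 9 lymphocyte genes (median 0.208, adjusted p = 0.366) had no member past the threshold.

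**Figure D1:**
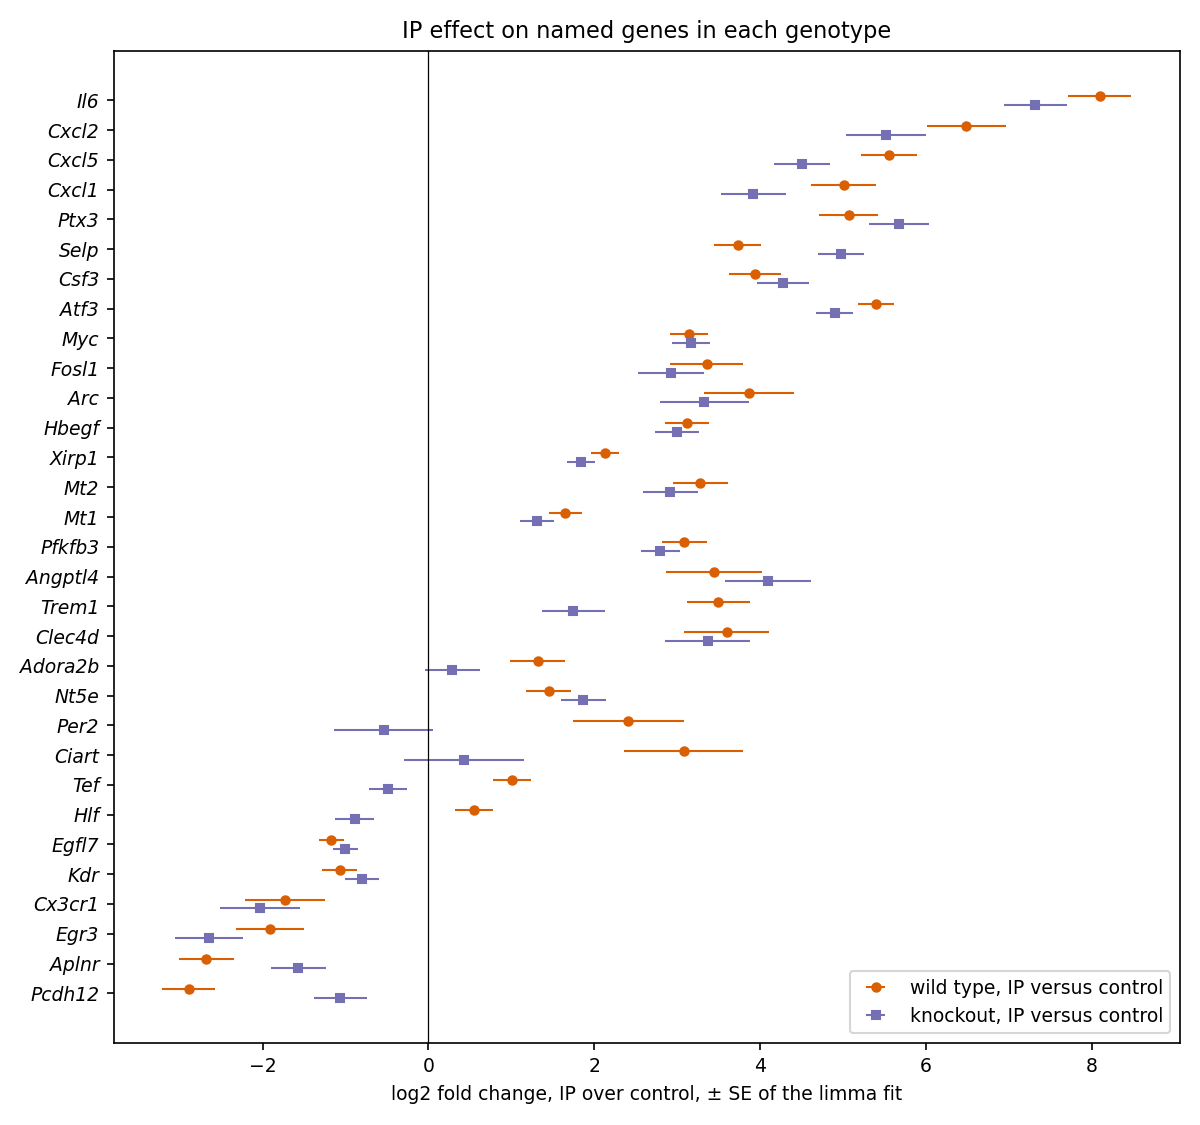
Log2 fold change of named genes after IP (horizontal axis), with circles for wild-type hearts, squares for knockout hearts and bars for the SE from limma. Il6 sits at 8.10 in wild type and 7.32 in knockout, while Per2 sits at 2.41 and −0.54, a difference that did not pass (adjusted p = 0.495).

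The comparison of IP with control hearts in the knockout asks how the ventricle responds when the receptor is absent. Of the separate genes past the threshold, Il6 had the largest rise, 160-fold (7.32 ± 0.38, limma adjusted p = 2.7e-08, n = 3 arrays per group), followed by Ptx3 at 51.3-fold (5.68 ± 0.36) and Cxcl2 at 45.8-fold (5.52 ± 0.48). As in wild type, whether the control signals of the risers lie above background was not tested, and where they are low the fold changes and ranks depend on the offset. Selp and Sele, the selectins with which endothelium catches leukocytes, rose by 4.98 ± 0.28 and 3.67 ± 0.33. Socs3, the feedback inhibitor of Il6 signalling, rose by 4.64 ± 0.26, Atf3 by 4.90 ± 0.22 and Csf3 by 4.28 ± 0.31. Otud1, a deubiquitinase, rose by 3.61 ± 0.19. Of the genes that fell, Egr3 changed by −2.64 ± 0.41 log2, G0s2, which restrains fat breakdown, by −2.56 ± 0.26, and Hey1, a target of Notch signalling, by −1.81 ± 0.20. In each of these genes all 3 IP arrays lay on 1 side of all 3 control arrays.

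By limma, 1705 genes passed between knockout IP and control hearts, 677 higher and 1028 lower. The count was 948 without the third knockout IP array and 1097 without the third knockout control array. Of those past the threshold, 345 were at least 2-fold higher and 166 at least 2-fold lower. Arrays did not overlap in 32.2% of genes, against 10% by chance.

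In knockout IP hearts 25 of 28 cytokine and adhesion genes rose, or 26 adjusted over the list alone (median 2.77, camera adjusted p = 2.51e-48; adjusted p = 0.00207 with an estimated correlation). Of 14 neutrophil markers 11 rose, or 13 adjusted over the list alone (median 2.54, adjusted p = 2.63e-15; adjusted p = 0.067 with an estimated correlation). Mmp8, the neutrophil collagenase, rose by 3.51 ± 0.58, and Il1r2, a decoy receptor for interleukin 1, by 3.40 ± 0.46. Of 14 interferon genes 3 rose (median 0.484, adjusted p = 2.06e-05; adjusted p = 0.33 with an estimated correlation), with Cxcl10 at 2.27 ± 0.22, Ifit1, an antiviral protein, at 1.55 ± 0.30 and Irf1 at 1.04 ± 0.15. Of 16 monocyte and macrophage genes 2 rose and 1 fell (median 0.0745, adjusted p = 0.0668; adjusted p = 0.0333 and 0.0437 without the first or the third knockout IP array, 0.019 and 0.0416 without the third knockout control or the third wild-type control array, and 0.00334 with the beta-actin covariate). Cd14 rose by 2.47 ± 0.13 and the mannose receptor Mrc1 by 0.68 ± 0.14. Of 30 immediate-early genes 15 rose and 3 fell, or 16 and 6 adjusted over the list alone (median 0.751, adjusted p = 1.72e-09; adjusted p = 0.0415 with an estimated correlation). Arc rose by 3.33 ± 0.54 and Myc by 3.17 ± 0.23. Klf2 (−1.34) and Klf4 (−1.27) were the fallers beside Egr3, chosen after their values were seen. Of 13 cAMP targets 4 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.633, adjusted p = 0.000634; adjusted p = 0.0415 with an estimated correlation). Pde4b rose by 1.76 ± 0.16, and Adrb1, the main adrenergic receptor of heart muscle, fell by 0.77 ± 0.15 log2.

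Of 14 cardiac stress genes 10 rose in knockout IP hearts, or 11 adjusted over the list alone (median 1.05, adjusted p = 3.83e-15; adjusted p = 0.0162 with an estimated correlation), with Xirp1 at 1.84 ± 0.17 and Timp1, an inhibitor of matrix proteases, at 1.45 ± 0.20. Of 13 antioxidant genes 4 rose, or 5 adjusted over the list alone (median 0.0761, adjusted p = 0.00233; adjusted p = 0.119 with an estimated correlation); Mt2 rose by 2.92 ± 0.33 and Mt1 by 1.31 ± 0.20. Of 16 p53 and growth-arrest genes 6 rose (median 0.114, adjusted p = 0.00196; adjusted p = 0.189 with an estimated correlation), among them Gadd45g, a stress sensor, at 1.68 ± 0.28. In the hypoxia list 6 of 22 genes rose and 2 fell, or 6 and 3 adjusted over the list alone (median 0.0427, adjusted p = 0.00408; adjusted p = 0.327 with an estimated correlation). Angptl4 rose by 4.10 ± 0.52 and Pfkfb3 by 2.80 ± 0.24. Of 15 heat shock genes 3 rose (median 0.246, adjusted p = 0.00324; adjusted p = 0.423 with an estimated correlation; adjusted p = 0.0955 without the third knockout IP array), among them Hspb1 at 0.67 ± 0.11 (adjusted p = 0.0578 with the mean of all probe sets). Of 16 endoplasmic reticulum stress genes 3 rose (median 0.172, adjusted p = 0.00591; adjusted p = 0.423 with an estimated correlation; adjusted p = 0.0523 without the second knockout control array), including Ppp1r15a at 1.65 ± 0.13 and Atf4, which drives the stress response, at 0.71 ± 0.12.

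The clock list did not pass in knockout IP hearts: 1 of 19 genes rose and 2 fell, or 2 and 2 adjusted over the list alone, with a median of 0.0886, a mean of −0.000494 and an adjusted p of 0.324 by camera. Nfil3, which represses clock outputs, rose by 2.00 ± 0.28. Per2 had a change of −0.54 ± 0.60 (adjusted p = 0.625), which was −1.74 and passed with the beta-actin ratio of each array as a covariate (adjusted p = 0.0249), and Per1 one of −0.17 ± 0.16 (adjusted p = 0.569). In the adenosine pathway 4 of 13 genes rose and 3 fell (median −0.0629, mean 0.12, adjusted p = 0.467), with Nt5e higher by 1.87 ± 0.27. Changes of the receptors were 0.29 ± 0.33 for Adora2b (adjusted p = 0.635), −0.13 ± 0.28 for Adora1 (adjusted p = 0.826) and 0.04 ± 0.26 for Adora2a (adjusted p = 0.951). With 1 array left out these ranged from −0.07 to 0.52, from −0.38 to 0.08 and from −0.18 to 0.24, while Per2 ranged from −1.38 to 0.09 and Per1 from −0.33 to −0.05.

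Lists of energy metabolism and muscle did not pass in knockout IP hearts. The cardiomyocyte list had a median of −0.0391 (adjusted p = 0.707) and the respiratory list one of −0.0424 (adjusted p = 0.88), with no member of either past the threshold; Ldb3, a Z-disc protein, had a change of −0.13 ± 0.06. Glycolysis had 2 of 20 genes higher, or 2 higher and 2 lower adjusted over the list alone, with a median of −0.0687, a mean of 0.0967 and an adjusted p of 0.928. Fatty acid oxidation had 2 of 22 higher and 1 lower (median −0.0153, mean 0.0743, adjusted p = 0.386; adjusted p = 0.0373 without the first knockout IP array); Ppargc1a rose by 0.90 ± 0.12. Endothelial genes had 1 of 16 higher and 4 lower, with a median of −0.0177 while camera pointed up (adjusted p = 0.976). Kdr changed by −0.80 ± 0.21, and Esam, an endothelial adhesion molecule, by 0.51 ± 0.10. The call of Kdr ended without the first or the third knockout IP array (adjusted p = 0.0629 and 0.0742), without the third knockout control array (−0.49, adjusted p = 0.0658) and with the beta-actin covariate (−0.43, adjusted p = 0.135). It also ended without an intensity trend (0.0676) and with zeros kept (0.068), and keeping zeros ended those of Angptl4, Cd14 and Klf4 in knockout as well (0.0587, 0.189 and 0.718). Ion channels had 1 of 19 higher and 2 lower, or 1 and 3 adjusted over the list alone (median −0.0645, adjusted p = 0.674), mural genes 3 of 11 lower (median −0.168, adjusted p = 0.249) and fibroblast genes 1 of 14 higher, or none adjusted over the list alone (median −0.0939, adjusted p = 0.997). Adipocyte genes had 1 of 5 higher (median 0.289, adjusted p = 0.226; by fry adjusted p = 0.0312, higher). The atrial (median 0.246, adjusted p = 0.297; adjusted p = 0.0464 without the third knockout control array), lymphocyte (median 0.0612, adjusted p = 0.603) and erythroid lists (median 0.0719, adjusted p = 0.467) had no member past the threshold.

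**Figure D2:**
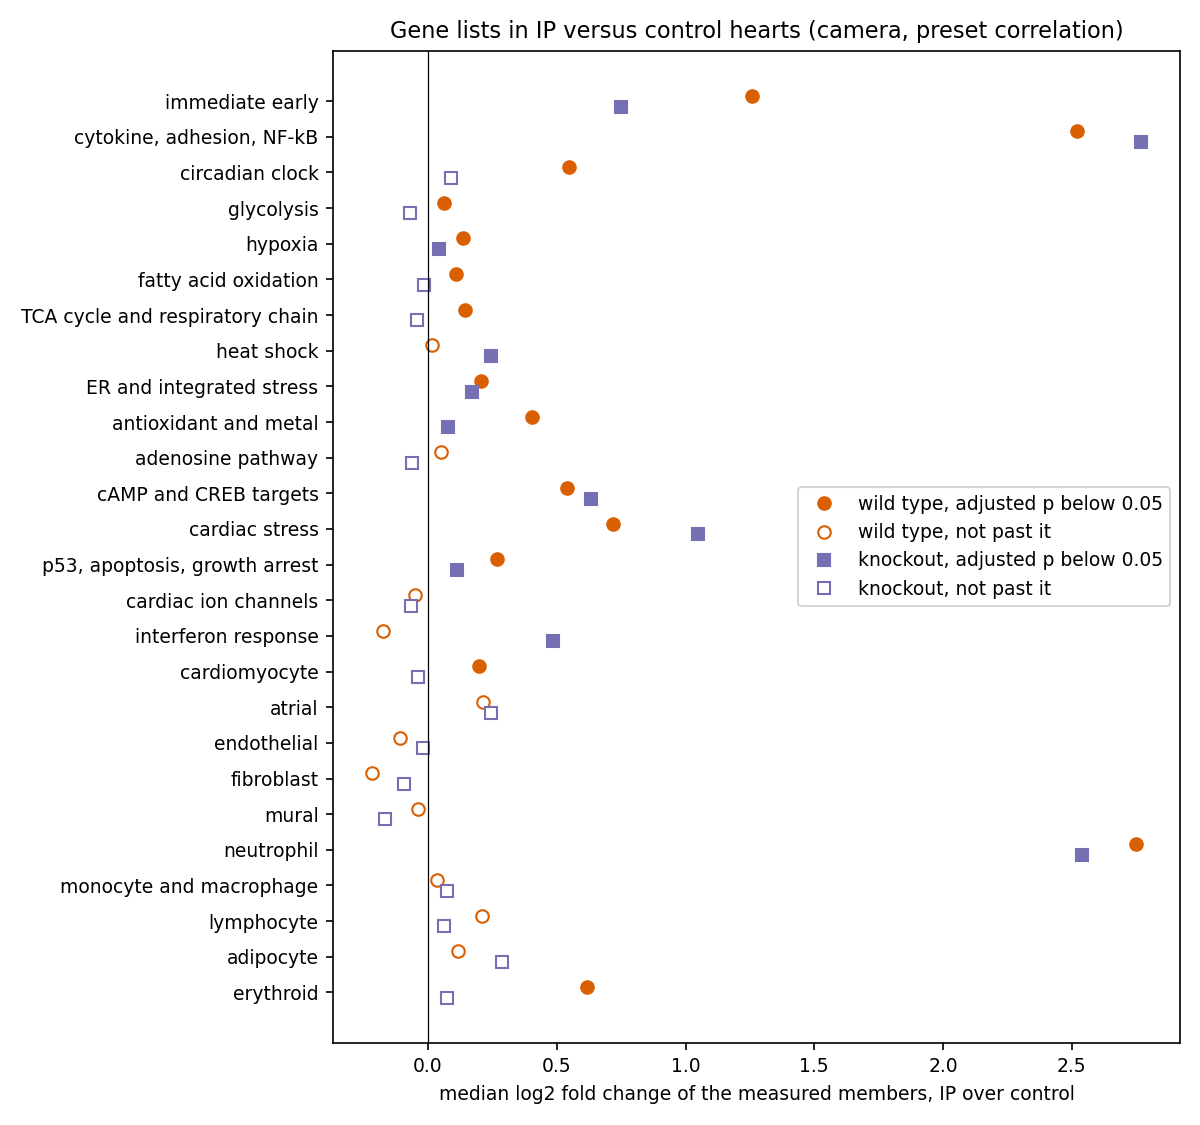
Median log2 fold change of the measured genes of each list after IP (horizontal axis), with circles for wild-type hearts, squares for knockout hearts and filled marks where camera passed with the preset correlation. The neutrophil list sits at 2.75 in wild type and 2.54 in knockout, while the cardiomyocyte list sits at 0.197 and −0.0391, and quantile normalization ends its call in wild type.

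The difference between the genotypes in their IP effect asks which responses to preconditioning depend on the receptor. By limma no gene passed: 0 of 14044, with 1105 at an unadjusted p below 0.05 and a smallest adjusted p of 0.325. In simulated data with few genes changed and no correlation between genes, limma recovered 44.8% of differences of 1 log2 in this comparison. The genes with the smallest p were Parn, a poly(A) nuclease (−0.94 ± 0.18, knockout minus wild type), Sugp1, a splicing factor (−0.76 ± 0.15), Tmx1, a thioredoxin of the endoplasmic reticulum (−0.75 ± 0.13), Hmgb1, a chromatin protein released by injured cells (−0.67 ± 0.13), and Rflnb, a partner of filamin (0.66 ± 0.13). Adora2b had a difference of −1.03 ± 0.46 (adjusted p = 0.619), Adora1 one of −0.71 (adjusted p = 0.703) and Adora2a one of −0.01 (adjusted p = 0.997). Without the second wild-type control array Adora1 was at −0.42, and with 1 array left out Adora2a ranged from −0.23 to 0.19. Per2 had −2.95 ± 0.90 and Per1 −0.70 ± 0.23 (adjusted p = 0.495 for both). The fit with the beta-actin ratio of each array as a covariate was chosen after the data were seen. That ratio did not overlap between knockout and wild-type IP arrays, so this fit cannot separate RNA quality from genotype after IP. With it 2 genes passed. They were Per2 at −5.04 ± 0.63 and Socs3 at 1.70 ± 0.22 (adjusted p = 0.0212 for both), where Socs3 otherwise had 0.92 ± 0.37 (adjusted p = 0.58), or 0.59 without the second knockout control array.

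The genes that moved with IP overlapped between the genotypes. Of 918 genes higher in wild type and 677 higher in knockout, 516 were the same genes, against 44.3 by chance; of 1410 and 1028 lower genes, 598 were shared, against 103. Over all 14044 genes the changes correlated across genes at r = 0.709 with 70.1% of the same sign, and genes are not independent replicates. In the average IP effect 3676 genes passed by limma. Among 349 genes at least 2-fold higher in the average effect, the mean change was 1.80 in wild type and 1.78 in knockout (exact permutation p = 0.925, two-sided, 400 permutations). Among 147 genes at least 2-fold lower, it was −1.26 and −1.21 (exact permutation p = 0.66, two-sided). Il6 rose 209-fold on average over the genotypes (7.71 ± 0.27, limma adjusted p = 1.52e-10), from control signals that were not tested against background. Upk3b and Aplnr changed by −2.14 and −2.12 log2 on average.

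As groups, 9 lists differed between the genotypes in their IP effect by camera, and by fry and by camera with an estimated correlation 0 did. Cardiomyocyte genes had a median difference of −0.207 (adjusted p = 2.6e-11; adjusted p = 0.373 with an estimated correlation) and respiratory genes one of −0.173 (adjusted p = 1.03e-08; adjusted p = 0.373 with an estimated correlation). By limma no member of either passed over all genes, while 13 of 22 and 6 of 23 were lower adjusted over the list alone. Actc1 had −0.29 ± 0.08. Both calls ended with quantile normalization (adjusted p = 0.714 and 0.923), which turned the respiratory list to the opposite direction. They cannot be told apart from the higher total signals of the wild-type IP arrays given above. The ratio of 3' to 5' beta-actin signal, a sign of RNA quality, was lower in knockout than in wild-type arrays after IP (log2 −0.413; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows), and so was that of Gapdh (log2 −0.122; exact permutation p = 0.1, two-sided). With the beta-actin ratio as a covariate both calls stayed (adjusted p = 1.2e-07 and 4.23e-07). The ratio did not overlap between knockout IP (0.8405 to 0.9483) and wild-type IP arrays (1.222 to 1.388). Its slope came from the spread within groups, which was largest in knockout control hearts (SD 0.263). This fit therefore cannot separate RNA quality from genotype after IP. Interferon genes had a median difference of 0.5 (adjusted p = 0.000167; adjusted p = 0.488 with an estimated correlation), with Ifit1 at 1.25 ± 0.43 and Ifit2 at 1.17 ± 0.39. Without the first knockout IP array these were 0.80 and 0.82, and the list had an adjusted p of 0.026. Immediate-early genes had −0.314 (adjusted p = 0.00299; adjusted p = 0.373 with an estimated correlation), with Jund at −0.87 ± 0.19, and this call ended with the beta-actin covariate (adjusted p = 0.331). Clock genes had −0.375 (adjusted p = 0.0402; adjusted p = 0.373 with an estimated correlation), with the output genes Tef at −1.50 ± 0.32 and Hlf at −1.43 ± 0.32 (adjusted p = 0.325 for both by limma); adjusted over the list alone 4 of 19 were higher and 9 lower. The clock call ended without the first knockout IP array (adjusted p = 0.114), the first or the second knockout control array (0.0771 and 0.123), the third wild-type IP array (0.0855) or the first or the third wild-type control array (0.0538 and 0.056).

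The calls of fatty acid oxidation, glycolysis, antioxidant and fibroblast genes in this difference ended when certain single arrays were left out. Fatty acid oxidation had a median difference of −0.11 (camera adjusted p = 0.00796; adjusted p = 0.649 with an estimated correlation), which quantile normalization ended (adjusted p = 0.631). Its adjusted p was 0.15, 0.0693 and 0.267 without the first knockout IP, the first knockout control or the second wild-type control array. Glycolysis had −0.174 (adjusted p = 0.0291; adjusted p = 0.373 with an estimated correlation; 0.488 with quantile normalization), antioxidant genes −0.244 (adjusted p = 0.0417; adjusted p = 0.373 with an estimated correlation; 0.208 with quantile normalization) and fibroblast genes 0.139 (adjusted p = 0.0462; adjusted p = 0.683 with an estimated correlation; 0.102 with quantile normalization). The glycolysis call ended without the second knockout control array (adjusted p = 0.0731), the third wild-type IP array (0.0734) or the first or the second wild-type control array (0.0537 and 0.0628), and with the beta-actin covariate (0.16). The antioxidant call ended without the first or the second knockout IP array (0.147 and 0.11), the second knockout control array (0.123), the third wild-type IP array (0.153) or the first or the second wild-type control array (0.0537 and 0.267). The fibroblast call ended without the first or the second knockout IP array (0.147 and 0.12), the second knockout control array (0.185), the first or the third wild-type IP array (0.151 and 0.167) or the second or the third wild-type control array (0.0883 and 0.555), and with replicate numbers as a block (0.0548).

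Other lists did not pass in the difference between the genotypes but did under some settings. Cytokine and adhesion genes had a median difference of 0.0656 and a mean of −0.0393 (camera pointed up, adjusted p = 0.781), and with the beta-actin covariate they passed, higher in knockout (adjusted p = 0.000473). With that covariate monocyte and macrophage genes (median −0.0115, mean 0.058, adjusted p = 0.523; 0.00944 with the covariate), heat shock genes (median 0.0487, adjusted p = 0.0829; 0.00131) and endothelial genes (median 0.173, adjusted p = 0.067; 0.0322) passed upward too. Neutrophil markers had a median of −0.28 (adjusted p = 0.87) and passed downward without the third wild-type control array (0.0136). Erythroid genes (median −0.544, adjusted p = 0.109) passed downward without that array (0.00249) or the third knockout control array (0.0389). Heat shock genes also passed without the first or the second knockout IP array (0.026 and 0.0113), the third knockout control array (0.0328) or the first or the second wild-type control array (0.0155 and 0.011), with quantile normalization (0.0271) and with replicate numbers as a block (0.0425). Endothelial genes passed without the third knockout IP (0.049), the third knockout control (0.0376) or the first wild-type control array (0.0125), and with no filter on low values (0.0491). Monocyte and macrophage genes passed without the first wild-type control array (0.0155). Cardiac stress genes (median 0.172, adjusted p = 0.109) passed without the second knockout IP array (0.0073) or the first wild-type IP array (0.0181).

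**Figure D3:**
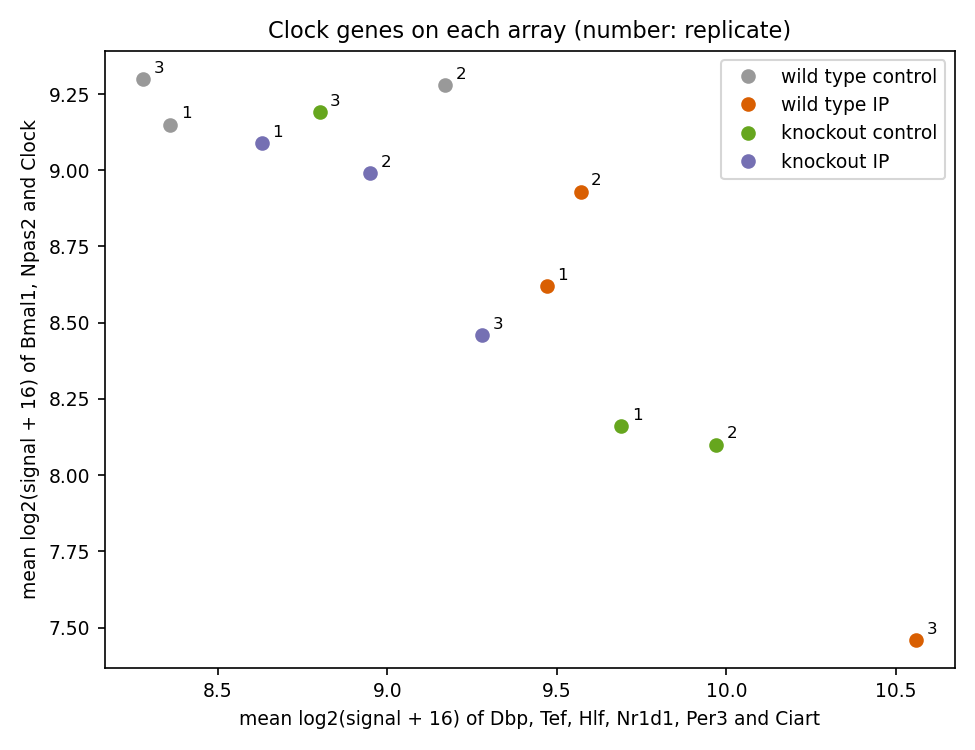
Mean log2(signal + 16) of the activators Bmal1, Npas2 and Clock (vertical axis) against that of the clock output genes Dbp, Tef, Hlf, Nr1d1, Per3 and Ciart (horizontal axis), with 1 point per array, coloured by group and numbered by replicate. The third wild-type IP array lies lowest, at 7.46 for the activators and 10.56 for the outputs.

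The comparison of knockout with wild type in control hearts asks what loss of the receptor changes without IP. By limma 5 genes passed, all lower in the knockout, with 926 at an unadjusted p below 0.05. Pttg1, which holds sister chromatids together as securin, was at 0.0713 of the wild-type level (−3.81 ± 0.08, adjusted p = 2.65e-13, n = 3 arrays per group). Cyfip2, a regulator of actin branching, was at 0.108 (−3.21 ± 0.24), Rab4a, a GTPase of endosome recycling, at 0.315 (−1.67 ± 0.14) and Mrpl55, a mitochondrial ribosomal protein, at 0.576 (−0.79 ± 0.10). The fifth was 2610507I01Rik (−3.02 ± 0.31), which the rule passes over and which was named after its value was seen. In these genes all 3 knockout arrays lay below all 3 wild-type arrays, and all 5 passed in each of the 12 fits that left out 1 array, while the call of Mrpl55 ended without an intensity trend (adjusted p = 0.0609). The count was 9 without the third knockout control array and 9 without the first wild-type control array. Arrays did not overlap in 12.2% of genes, against 10% by chance. Adora2b had a difference of −0.42 ± 0.33 (adjusted p = 0.869), or −0.06 without the first knockout control array, Per2 one of 1.77 ± 0.67 (adjusted p = 0.683), Per1 one of 0.30 (adjusted p = 0.807), and Adora1 and Adora2a ones of 0.38 and 0.24 (adjusted p = 0.862 and 0.923). Without the second knockout control array Per2 was at 1.14, and with 1 array left out Per1 ranged from 0.18 to 0.46, Adora1 from 0.09 to 0.63 and Adora2a from 0.04 to 0.46. Of the lists, immediate-early genes had a median difference of 0.264 (camera adjusted p = 0.000945; adjusted p = 0.776 with an estimated correlation; adjusted p = 0.081 without the first knockout control array). Ier3, a survival gene, had 0.69 ± 0.16 (adjusted p = 0.324). The clock list did not pass, with 6 genes higher and 2 lower adjusted over the list alone, but did without the third knockout control array (adjusted p = 0.0141). Neutrophil markers had a median of 0.00555 while camera pointed down (adjusted p = 0.846), and they passed upward without the third wild-type control array (adjusted p = 0.0171). Without that array respiratory (0.00566), antioxidant (0.0171) and erythroid genes (0.0171) passed upward too. Heat shock genes (median −0.145, adjusted p = 0.0816) passed downward without the third knockout IP (0.0487), the third knockout control (0.0221), or the first or the second wild-type control array (0.00234 and 0.00169), and with replicate numbers as a block (0.0133). Without the first wild-type control array fatty acid oxidation passed upward (0.00174) and fibroblast (0.000643) and monocyte and macrophage genes (0.0459) downward. Without the second, lymphocyte genes passed upward and hypoxia genes downward (0.0392 for both), and without the third knockout control array atrial genes passed downward (0.0141).

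The comparison of knockout with wild type after IP asks how the preconditioned hearts differ by genotype. By limma 16 genes passed, 4 higher and 12 lower in the knockout. Pttg1 was at 0.0589 of the wild-type level (−4.09 ± 0.08, adjusted p = 9.51e-14, n = 3 arrays per group), Cyfip2 at 0.0779 (−3.68 ± 0.24) and Rab4a at 0.329 (−1.60 ± 0.14). Tmx1 was at 0.596 (−0.75 ± 0.09). These, with 2610507I01Rik, were the 5 genes that passed in each of the 12 fits that left out 1 array. The beta-actin covariate ended the calls of Tmx1 (−0.55, adjusted p = 0.313) and 2610507I01Rik (−2.70, adjusted p = 0.144), and that of Tmx1 ended without an intensity trend (0.086). Ramp1, a co-receptor for calcitonin gene-related peptide, was at 0.449 (−1.16 ± 0.16, adjusted p = 0.00978), with adjusted p = 0.0761 without the first knockout IP array and 0.054 and 0.0871 without the first or the third wild-type IP array. Its call also ended with the mean of all probe sets (−0.92, adjusted p = 0.433). So it did, at nearly the same size, with the beta-actin covariate (−1.14, adjusted p = 0.313), zeros kept (−1.16, 0.751) and no intensity trend (−1.16, 0.086). All 3 knockout arrays lay below all 3 wild-type arrays in each of these genes. Adora2b was at 0.366 without passing (−1.45 ± 0.33, adjusted p = 0.0958; adjusted p = 0.0369 in a fit of these groups alone), Per2 had −1.18 ± 0.60 (adjusted p = 0.437; −0.71 without the third wild-type IP array) and Per1 −0.41 ± 0.16 (adjusted p = 0.31). Adora1 and Adora2a had −0.33 and 0.23 (adjusted p = 0.673 and 0.772), with Adora1 at −0.21 without the second knockout IP array and Adora2a from 0.02 to 0.43 with 1 array left out.

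The count of genes between knockout and wild type after IP moved with single arrays. Through the estimate of spread alone, it was 39 without the third wild-type control array and 26 without the third knockout control array. It was 6, 6 and 9 without the first, the second or the third knockout IP array, and 7, 8 and 5 without the first, the second or the third wild-type IP array. Arrays did not overlap in 19.6% of genes, against 10% by chance. As groups, cardiomyocyte genes were lower in knockout (median −0.207, camera adjusted p = 2.9e-12; adjusted p = 0.491 with an estimated correlation) and so were respiratory genes (median −0.131, adjusted p = 3.59e-07; adjusted p = 0.698 with an estimated correlation). Quantile normalization ended both calls and turned both to the opposite direction (adjusted p = 0.793 and 0.171). These small differences cannot be told apart from the higher total signals of the wild-type IP arrays. Adjusted over the list alone 16 of 22 and 12 of 23 genes were lower; Tnnt2, the cardiac troponin T, had −0.23 ± 0.05 and Cox5b, of cytochrome c oxidase, −0.25 ± 0.06. The 3' to 5' beta-actin ratio was lower in knockout IP than in wild-type IP arrays (log2 −0.413). With it as a covariate both calls stayed (adjusted p = 1.28e-06 and 6.48e-05). As said for the difference in IP effect, this fit cannot separate RNA quality from genotype after IP. With this covariate cytokine and adhesion genes, with a median of 0.0536 (adjusted p = 0.408), passed as higher in knockout (adjusted p = 7.31e-08). So did monocyte and macrophage (0.00279), fibroblast (0.00943), endothelial (0.0247) and heat shock genes (0.0304), while fatty acid oxidation (0.000567) and clock genes (0.0101) passed as lower. Interferon genes were higher in knockout (median 0.426, adjusted p = 1.51e-06; adjusted p = 0.698 with an estimated correlation), 5 of 14 adjusted over the list alone, with Ifit2 at 1.09 ± 0.27 (adjusted p = 0.124) and Rsad2 at 0.75 ± 0.21 (adjusted p = 0.15). Without the first knockout IP array these were 0.74 and 0.47, and the interferon list had an adjusted p of 0.00904. Fatty acid oxidation (median −0.083, adjusted p = 0.0677) passed as lower without the second or the third knockout IP array (0.0442 and 0.00438) or the first or the second wild-type control array (0.0457 and 0.0465). Endothelial genes (median 0.131, adjusted p = 0.0638) passed as higher without the second or the third knockout IP (0.0465 and 0.0351), the third wild-type IP (0.0319), or the first or the second wild-type control array (0.0439 and 0.0465), and with no filter on low values (0.0355). Mural genes (median −0.212, adjusted p = 0.108) passed as lower without the second knockout IP or the first wild-type IP array (0.0214 and 0.0108).

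Averaged over both treatments, 20 genes differed between the genotypes by limma, 6 higher and 14 lower in the knockout. Pttg1 had −3.95 ± 0.06 (adjusted p = 9.7e-16), Cyfip2 −3.45 ± 0.17, Rab4a −1.64 ± 0.10 and Mrpl55 −0.70 ± 0.07. Ide, the insulin-degrading enzyme, was higher by 0.73 ± 0.10. These, with 2610507I01Rik, were the 6 genes that passed in each of the 12 fits that left out 1 array. The call of Ide ended without an intensity trend (adjusted p = 0.0864) and with zeros kept (0.0951). Kcne1, a subunit of a repolarizing potassium channel, had −1.10 ± 0.17 (adjusted p = 0.0219), with adjusted p between 0.0537 and 0.067 without the third knockout IP, the second knockout control, or the first or the second wild-type IP array. Its call also ended with the beta-actin covariate (−0.85, adjusted p = 0.405), the mean of all probe sets (0.0716), zeros kept (0.0951) and no intensity trend (0.0572). The count of genes was 40 without the third knockout control array and 35 without the third wild-type control array. It was 11, 11 and 10 without the first, the second or the third knockout IP array, 12 and 8 without the first or the second knockout control array, and 9, 6 and 13 without the first, the second or the third wild-type IP array. Of 16 of these genes with a position, 8 lie within 20 Mb of Adora2b on chromosome 11, or 50%, against 3.35% of the 12571 tested genes with a position. Among them, Pttg1 starts at 43263687, Cyfip2 at 46037281 and Mrpl55 at 59018712. Rab4a lies on chromosome 8 and Ide on chromosome 19.

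**Figure D4:**
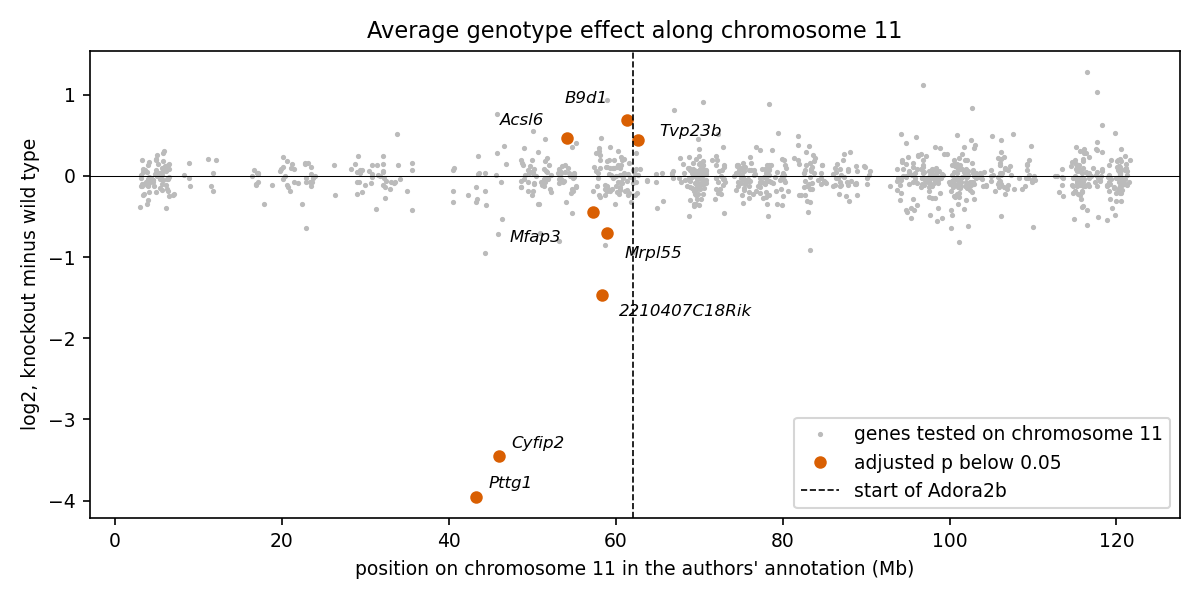
Log2 difference between knockout and wild type averaged over both treatments (vertical axis) of the genes tested along chromosome 11 (horizontal axis, Mb), with large points for genes past the threshold and a dashed line at the start of Adora2b. Pttg1 at −3.95 and Cyfip2 at −3.45 lie 18.8 and 15.9 Mb from Adora2b.

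**Figure D5:**
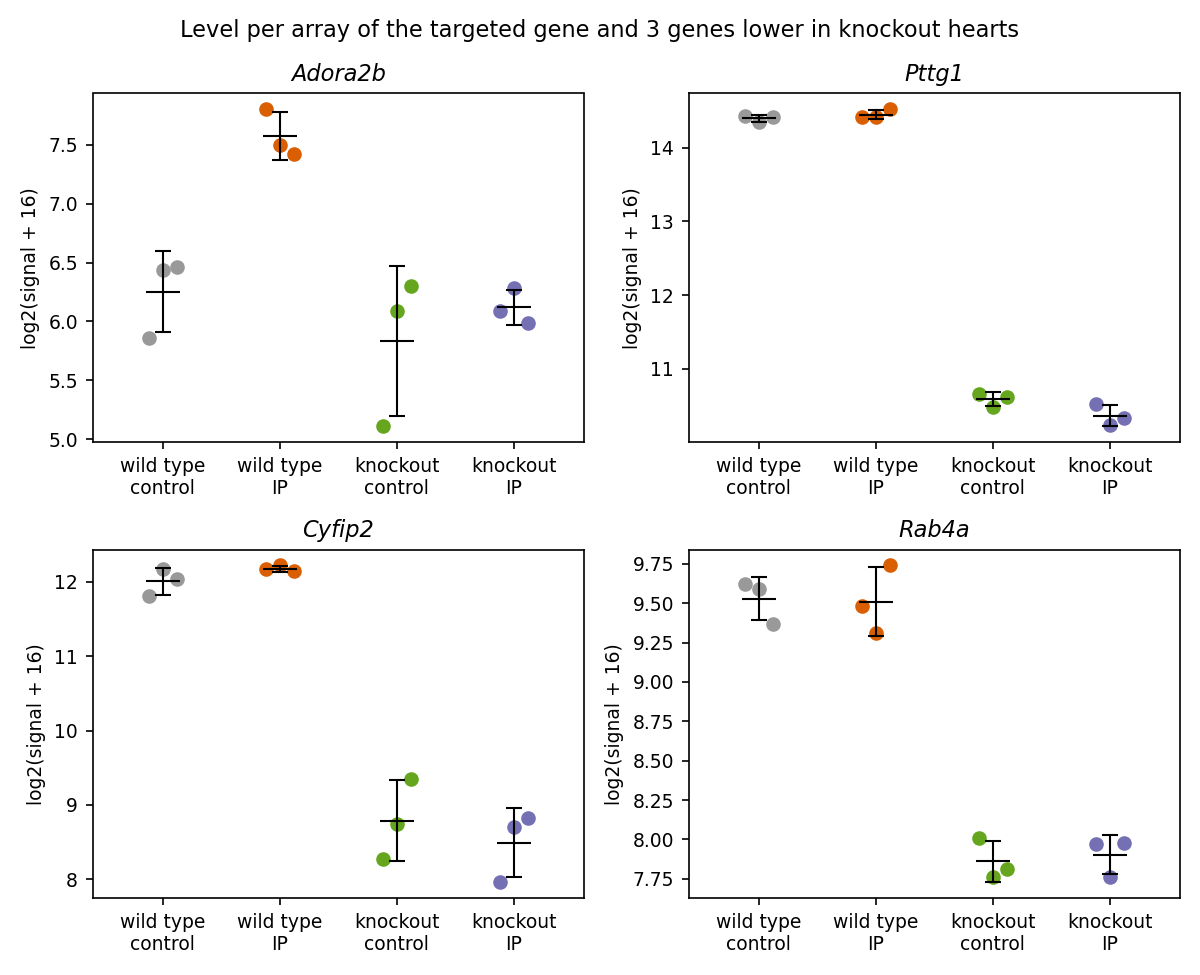
Log2(signal + 16) of Adora2b, Pttg1, Cyfip2 and Rab4a (vertical axes) on each array of the 4 groups, with 1 point per array, lines for the means and bars for the SD. Every knockout array lies below every wild-type array of the same treatment for Pttg1, Cyfip2 and Rab4a.

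The authors' deposited table gives its own calls per probe set. For IP in wild type, the authors' deposited table has 1979 probe sets higher and 3425 lower, and its list of changes of at least 2-fold holds 755, of which 754 have the same sign here and 644 pass here. For IP in knockout, the authors' deposited table has 1884 higher and 2736 lower, and of its 2-fold list of 644, all have the same sign here and 565 pass. For knockout against wild type after IP, 17 of the 73 probe sets in the 2-fold list of the authors' deposited table pass here, and for control hearts 10 of 38. For the difference in IP effect, the 30 probe sets in the 2-fold list of the authors' deposited table include Per1 (−1.37), Tef (−1.05), Hlf (−1.22) and Adora2b (−1.08). Per2 is among them with −1.02 and −1.05. The listed probe sets of Tef and Per2 are not those that represent these genes here. On the listed ones the fit here gave −0.76 ± 0.39 for Tef, and −1.67 ± 0.52 and −1.85 ± 0.51 for Per2. All 30 from the authors' deposited table have the same sign here, 23 have an unadjusted p below 0.05 here, and 0 pass by limma. Over 27022 probe sets, log2 differences correlated with those of the authors' deposited table at r between 0.592 for that difference and 0.861 for IP in wild type, across probe sets that are not independent.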

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

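The tests of the clock genes and the counts over other splits of the arrays were chosen only after the results were seen.

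By limma's camera with the preset correlation, 9 gene lists differed between the genotypes in their response to IP, which is why they are given here. Their median differences, knockout minus wild type, were −0.314 for immediate-early genes, −0.375 for clock genes, −0.174 for glycolysis, −0.11 for fatty acid oxidation, −0.173 for the tricarboxylic acid cycle and oxidative phosphorylation, −0.244 for antioxidants, −0.207 for cardiomyocyte genes, 0.139 for fibroblast genes and 0.5 for interferon genes. None of the 9 passed with an estimated correlation, where adjusted p-values were between 0.373 and 0.683, and fry called 0 lists. Quantile normalization ended the calls of glycolysis, fatty acid oxidation, the respiratory list, antioxidants, cardiomyocytes and fibroblasts. By limma 0 genes passed in this difference, with 1105 at an unadjusted p below 0.05. Over 100 splits with the genotype labels moved within each treatment, all 100 gave at least as many, as a count of 0 requires, and the highest other gave 36, so the splits decide nothing here.

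Clock genes differed between the genotypes in their IP effect as a list by camera with the preset correlation. That call ended with an estimated correlation and when certain single arrays were left out. By limma none of them passed singly without the beta-actin covariate. The output genes Dbp, Tef, Hlf, Nr1d1, Per3 and Ciart had a mean change with IP of 1.27 ± 0.43 log2 in wild type and −0.53 ± 0.43 in knockout (difference −1.80 ± 0.60), while the activators Bmal1, Npas2 and Clock had −0.90 ± 0.43 and 0.36 ± 0.43 (difference 1.27 ± 0.61). The ratios to the SE in knockout were −1.25 and 0.851, so a movement of either arm there is not shown. Within groups the activators and outputs also moved against each other from array to array. With group means removed, their correlation over 12 arrays was r = −0.828 (exact permutation p = 0.0185) and rho = −0.846 (exact permutation p = 0.0123, 1296 permutations within groups, two-sided), and r was −0.674 over 10 arrays without the 2 farthest from the median. It was the only relation across arrays computed. A candidate explanation is a different time of day of tissue collection between arrays, since this opposite movement is that of the daily clock. The hours are not given in the sources used here. Activators and outputs belong to the same loop, so any disturbance of it could move them oppositely. The correlation therefore does not single out collection time. A rise of clock genes with IP that needs the receptor stays open. The check written for it, control hearts that do not differ by genotype, cannot decide it, since receptor loss could also move levels without IP. The outputs were higher in knockout control hearts by 0.88 ± 0.43, a ratio to the SE of 2.07, with arrays that overlapped. Its own prediction is a weaker rise with IP in knockout. The outputs' difference of −1.80 ± 0.60 has that direction, but different collection times could give it too.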

How the results depend on the processing

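Keeping the run of zeros as deposited and the beta-actin ratio as a covariate were tests chosen only after the data were seen; the authors' per-array values were not run.

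Among genes named for their change with IP, 707 of 720 values in wild type and 489 of 492 in knockout kept direction and call with 1 array left out. Most of these genes were chosen for large changes past the threshold in these same data. The arrays left out include those of the other genotype, which alter only the estimate of spread. These shares therefore do not describe all genes called. Of the 36 values of the 3 genes given for the average IP effect, all stayed past the threshold with any 1 array left out. Left-out arrays gave 1420 to 2351 genes for IP in wild type, 948 to 1704 for IP in knockout, 5 to 9 for knockout against wild type in control hearts, 5 to 39 after IP, 0 to 0 for the difference, 3020 to 3477 for the average IP effect and 6 to 40 for the average genotype effect. In lists past the threshold they gave 11 to 17, 10 to 13, 0 to 5, 3 to 6 and, for the difference, 5 to 12. The level of Adora2b by genotype went from −1.05 to −0.76. Of the genes called, 1059 (45.5%) for IP in wild type and 785 (46%) for IP in knockout remained in all 12 such fits.

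With a 2-fold minimum, 567 genes passed for IP in wild type, 511 for IP in knockout, 7 for knockout against wild type after IP, 532 for the average IP effect and 8 for the average genotype effect. An offset of 64 gave 8 genes in control hearts. Without an intensity trend 4 genes passed after IP and 7 for the average genotype effect; with array weights these were 45 and 31; with zeros kept they were 6 and 6, and a fit of only the groups compared gave 74 after IP. The beta-actin covariate gave 1077 genes for IP in knockout, 3 after IP, 2 for the difference and 8 for the average genotype effect, and 10 lists after IP. Quantile normalization gave 4 lists for the difference and 1 after IP. With an estimated correlation 5, 4, 0, 0 and 0 lists passed for IP in wild type, IP in knockout, control hearts, after IP and the difference; by fry 13 passed for IP in wild type, 12 higher and 1 lower (endothelial genes), 8 for IP in knockout, 0 in control hearts, 1 after IP and 0 for the difference. For these counts by limma the cause was not tested, except that a 2-fold minimum removes genes by its construction.

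The changes that reversed were those of genes that did not pass, apart from Klf4 and Ier2. These became 1.55 and 1.67 for IP in wild type with zeros kept, since both lie in the run of zeros. With the mean of all probe sets Adora1 became 0.15 and Adora2a −0.04 for IP in knockout. With an array left out, Adora2a ranged from −0.18 to 0.24 for IP in knockout, from −0.1 to 0.26 for IP in wild type and from −0.23 to 0.19 for the difference. For IP in knockout Adora1 ranged from −0.38 to 0.08, Adora2b from −0.07 to 0.52 and Per2 from −1.38 to 0.09. For the difference Adora2a became 0.04 with quantile normalization, 0.01 with array weights and 0.14 with the covariate, and 0 for IP in wild type with the covariate; the cause was not tested.

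With replicate numbers as a block 2 lists passed in control hearts. Correlations between arrays of the same number, over 18 pairs, ran from −0.0558 to 0.0761, and 0 were above 0.1, so the numbers do not pair the arrays. Simulated differences in IP effect of 0.5, 1 and 2 log2 were recovered in 7.46%, 44.8% and 80.3% of cases.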

Other observations

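The test of the positions of genes around Adora2b, the count of those with no other probe set and the counts over other splits of the arrays were chosen only after the results were seen.

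Further inflammatory genes, chosen after their values were seen, rose with IP. In wild type Ptgs2, the inducible cyclooxygenase, and Il1b, a cytokine of activated myeloid cells, each rose by 3.75 log2, Ccl2, which attracts monocytes, by 3.43, and Icam1, which binds leukocytes to endothelium, by 2.59. The value of Ptgs2 rests on 2 control arrays. Lcn2, an iron-sequestering protein of neutrophils, rose by 2.47 in wild type and 3.09 in knockout. S100a9, a protein of neutrophils, averaged 9.64 ± 2.25 log2 in wild-type control hearts, 13.02 ± 0.84 in wild-type IP hearts, 9.53 ± 0.58 in knockout control hearts and 12.58 ± 0.62 in knockout IP hearts (SD, n = 3). Its partner S100a8 averaged 9.32 ± 1.94, 12.35 ± 0.89, 9.36 ± 0.27 and 11.94 ± 0.57.

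Hypoxia targets split in wild type. Vegfa, a growth factor of vessels, changed by −0.65 and Egln3, an oxygen sensor, by −1.03, while Angptl4 rose by 3.45 ± 0.58; the falling genes were chosen after their values were seen. For Egln3 the difference in IP effect, knockout minus wild type, was 1.08 ± 0.24 (limma adjusted p = 0.327).

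Inflammatory genes rose after IP in both genotypes. Against a difference in RNA quality shared by both genotypes, the 3' to 5' beta-actin ratio was −0.0575 log2 in IP minus control arrays (exact permutation p = 0.626, two-sided). IP arrays ran from 0.8405 to 1.388 and control arrays from 0.885 to 1.398. The pooled value hides opposite shifts within the genotypes. Control and IP means were 1.196 and 1.301 in wild type, and 1.109 and 0.8879 in knockout. Against a lower share of cardiomyocyte RNA, the endothelial, fibroblast and mural medians in the average IP effect were −0.0113, −0.144 and −0.214, where a rise was predicted. The cardiomyocyte list had a median of 0.0731, where a fall was predicted. That value takes in the wild-type rise, which cannot be told apart from brighter wild-type IP arrays, so it alone decides nothing. A candidate source is infiltrating neutrophils or monocytes: the 14 neutrophil markers tested had a median of 2.7, none is in another list and 3 exceeded the median gene in wild-type control hearts, while the monocyte and macrophage median was 0.0882. The listed neutrophil markers Ly6g, Cxcr2, Retnlg and Camp were not among the genes tested. Ngp, another marker, averaged 6.86 and 7.25 log2 in wild-type control and IP hearts, and 6.35 and 8.58 in knockout. S100a9, which neutrophils make in abundance, averaged 9.64 and 13.02 log2 in wild-type control and IP hearts and 9.53 and 12.58 in knockout, with the third wild-type control array at 12.24, and the labels name no sorting of cells. Induction in resident heart cells, which the design allows, was not tested, nor was the surgery itself, which stays open because the labels call the controls both untreated and sham operated.

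Of the 16 genes with a position that differ between knockout and wild type in the average effect, 8 lie within 20 Mb of Adora2b. The others lie on other chromosomes. Against a variant under single probe sets, 83.3% of the other probe sets of the called genes within 20 Mb (5 of 6, from 4 of the 8 genes) had the same direction at an unadjusted p below 0.05; the other 4 genes have no other probe set above the filter, so for them this stays open. A strain variant around the targeted locus is a candidate explanation: by Fisher's exact test called genes were more frequent within 20 Mb of Adora2b (p = 1.51e-08, two-sided), and within 10 Mb (6 of 16, p = 2.48e-07). Loss of the receptor stays open. The genotype differences of the 8 near genes changed after IP, in their own direction, by a median of 0.037. The median of the genes' own SEs was 0.154. A median change within its SE of 0 had been written as speaking against loss of the receptor. That criterion was wrong, since 4 differences were larger and 4 smaller after IP, 3 of them beyond 2 SE, so the median decides nothing. Wild-type mice bought from a vendor, which the labels name beside littermates, could differ from the knockouts in background near Adora2b and elsewhere. That was not tested, nor was any explanation for the called genes on other chromosomes, Rab4a and Ide among them.

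Other splits of the same arrays were counted for each comparison by limma. Averaged over both genotypes, 3676 genes passed for IP, and 1 of 100 splits, the real one, gave as many (highest other 132). Regrouping these arrays at random therefore rarely gives such a count. This takes the arrays as independent samples, and the labels do not say whether they come from separate animals. For the average genotype effect, with 20 genes, 1 of 100 gave as many, the real one, but another gave 18. With 1 array left out the real count ranged from 6 to 40. This count therefore does not exclude chance for the 20 genes as a set. Only 6 of them passed in each of the 12 fits that left out 1 array. Comparisons of 3 with 3 arrays allow 10 splits, too few for a share below 0.05. There, IP in wild type gave 2328 genes in 1 of 10 splits (highest other 1), IP in knockout 1705 in 1 of 10 (highest other 0) and knockout against wild type after IP 16 in 1 of 10 (highest other 2). In control hearts 2 of 10 splits gave at least the 5 genes found. The other gave 26 and joined the first and the second knockout control arrays with the third wild-type control array. What these arrays share was not tested.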
